A study of Mus musculus with 7 samples.

How the data were processed

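The series holds 7 droplet libraries of mouse cells. The titles put 3 of them in a group with floxed Atad3a alleles (fl/fl 1 to 3) and 4 in a group called Ast KO (Ast KO 1 to 4), read here, with the series title, as a knockout of Atad3a in astrocytes. Atad3a encodes a protein of the inner mitochondrial membrane. The series title concerns stroke, while the sample labels name tumour cells as the source; the tissue region, the time after any lesion and the animal behind each library are not given in the sources used here. Cells were dissociated fresh, captured in droplets with 10x Genomics 3' reagents of version 3.1 and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. In this chemistry a unique molecular identifier (UMI) marks each captured transcript near its 3' end, so that PCR copies of a molecule are counted once.

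The deposited matrices hold raw UMI counts per gene and cell barcode, written by Cell Ranger 9.0.1 per the file headers. Per the submitters' processing notes, Cell Ranger 8.0.0 and Scanpy 1.9.6 were used, and the builds GRCm39 and mm10 are both named with no role, so no coordinates are given. The files pair 33696 gene identifiers with symbols, of which 32012 are also in the reference annotation used here. The authors' cell calling was already applied: the matrices hold 78018 barcodes, each with at least 500 UMIs. Free RNA was therefore not measured in empty droplets, and was followed through marker genes of astrocytes in the cells of other classes. No cell type annotation by the authors was used here.

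Cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet, as implemented in Scanpy 1.11.5. Its automatic threshold marked 0% of the cells in fl/fl 3 and in Ast KO 4, so in every library the highest scores were removed up to the expected share, which grows with the number of cells. This removed 6481 cells and left 70974. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes were chosen. Any mitochondrially encoded or haemoglobin genes, Xist, Tsix, the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, and Atad3a were then taken out of these. On the genes left, 30 principal components were fitted. Cells were joined to their 15 nearest neighbours and clustered with the Leiden method at resolution 1, with no integration across libraries. A cluster was named from markers fixed before the data were examined. A marker counted when it was at least 2-fold higher than in the other cells (with 10 CPM added to both levels) and was detected in at least 10% of the cluster's cells. Haemoglobin genes alone did not name a cluster erythroid, because haemoglobin was taken for free RNA in every library. A cluster stayed unnamed with fewer than 3 such markers, or with more markers of another class than of its own among its 10 leading genes. It also stayed unnamed with a low median UMI count and no marker of its own among those genes. By a threshold set after the data were seen, so did a cluster with more of the class's markers missed than met. This last threshold kept out clusters 5 and 33. The names are rebuilt here and can differ from the authors' own.

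UMI counts were summed per library and class, and each class with at least 20 cells in at least 3 libraries per group was tested with edgeR 4.0.16 (quasi-likelihood test, robust fit, TMM normalisation, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes of the class and a threshold of 0.05. Levels are given as edgeR's CPM of the summed class, counts scaled by the library's normalised size. Ast KO 4 had too few excitatory neuron-like cells and was left out of that class; oligodendrocyte precursor-like cells were not tested. A set of 32 gene lists, fixed before the data were examined, was tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2), which asks whether a list's genes moved more in a direction than the other genes did, with adjustment over the lists of a class. Each list was also tested with an estimated correlation and with fry. Another 22 lists of cell type markers were read in each class to follow RNA of other cells. Shares of cells were compared with a two-sided exact permutation test over all 35 splits of the 7 libraries, adjusted over 12 classes. A difference of the effect between astrocyte-like and microglia-like cells was tested in edgeR as an interaction with the library as a block.

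The genes named in the text follow a rule fixed before the data were examined. Atad3a is given in every tested class. In astrocyte-like cells, up to 10 genes in each direction were to be named by fold change among those past the threshold with at least 10 CPM and no overlap of the groups; where none passed, the 5 with the lowest p in each direction are named. In the other classes up to 3 genes in each direction are named, and from each list up to 4 members with the lowest p. The genes that lead unnamed clusters and the genes that show the sex of a library were chosen after their values were seen.

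Depth differs between libraries and classes. Total counts ran from 51635423 to 80183627 UMIs per library, while the astrocyte-like sums ran from 3452456 UMIs in Ast KO 1 to 34006607 in fl/fl 3, so fold changes in Ast KO astrocyte-like cells rest on fewer molecules. In simulated data the changed genes were drawn from those with a mean of at least 10 CPM, 100 for each fold. In data simulated from the astrocyte-like sums (14992 genes), edgeR recovered 64% of genes changed 2-fold and 96% of genes changed 4-fold, with 14 unchanged genes called. DESeq2 1.42.0 recovered 82% and 98% with 44 unchanged genes called. In data simulated from the microglia-like sums (13448 genes), edgeR recovered 56% and 95% with 9 unchanged genes called, and DESeq2 71% and 97% with 36. In data simulated from the ependymal-like sums (13355 genes), edgeR recovered 67% and 100% with 11, and DESeq2 68% and 99% with 18. These shares do not cover genes with lower counts. Each gene was simulated independently, so differences between libraries in cluster makeup or in RNA of other cells were not modelled. The alternatives tried were DESeq2, other size factors, no filter on low counts, mitochondrial limits of 10% and 40%, doublets kept, Leiden resolution 2, sums thinned to the smallest library, a replicate block, other denominators for shares, and leaving out each library in turn. After the data were seen, sex as a covariate, leaving out both fl/fl 3 and Ast KO 4, leaving out single clusters, a denominator of named classes and a minimum of 2000 UMIs per cell were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were also used.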

Results

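Single-cell transcriptomes of 3 fl/fl and 4 Ast KO libraries were compared to ask what deletion of Atad3a in astrocytes, in the setting of the series' work on stroke, does to astrocytes and to the cells around them. The libraries held between 10000 barcodes (Ast KO 1) and 12256 barcodes (Ast KO 4). Total counts ranged from 51635423 UMIs in Ast KO 4 to 80183627 in fl/fl 2. The median per barcode ran from 2060 UMIs in Ast KO 4 to 5205.5 in Ast KO 1. After filtering, 70974 cells formed 34 clusters, and 26 of these were assigned to 12 classes. These were astrocyte-like, oligodendrocyte-like, oligodendrocyte precursor-like, microglia-like, border macrophage-like, endothelial-like, pericyte-like, fibroblast-like, ependymal-like, choroid plexus epithelium-like, excitatory neuron-like and neural progenitor or neuroblast-like cells. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

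The libraries of a group were not alike. In Ast KO 4, cluster 32, led by Bc1, haemoglobin and mitochondrial transcripts, held 38.1% of the cells against at most 0.692% in any other library. The median mitochondrial share per barcode of Ast KO 4 was 7.15%, against 1.97 to 2.58% in the other Ast KO libraries and 3.12 to 5.58% in the fl/fl libraries. In Ast KO 3, clusters 25 and 33, led by pituitary hormone genes (Prl, Gh, Pomc and Cga), held 9.26% and 6.65% of the cells against at most 0.159% and 0.0185% elsewhere. Xist, the RNA that silences an X chromosome in female cells, stood at 685, 585 and 540 CPM in fl/fl 3, Ast KO 3 and Ast KO 4 and at most at 0.618 CPM in the other 4 libraries. These 4 held transcripts of Y-linked genes at 162 to 186 CPM. The haemoglobin level over all cells (224 to 1501 CPM in fl/fl, 1295 to 10530 CPM in Ast KO) varied within both groups.

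Atad3a itself was read in every class. In astrocyte-like cells it stood at 22.9, 25.4 and 29.2 CPM in fl/fl 1 to 3 and at 23.8, 25.6, 18.8 and 19.1 CPM in Ast KO 1 to 4, from 79 to 922 UMIs per library. The means were 25.8 ± 3.16 CPM (SD, n = 3) and 21.8 ± 3.39 CPM (SD, n = 4), a log2 fold change of -0.25 ± 0.16 (SE; edgeR adjusted p = 0.605). In microglia-like cells, which the labels do not name as targeted, the log2 fold change was -0.29 (edgeR adjusted p = 0.60). Over the 11 tested classes it ran from -0.52 in border macrophage-like cells to 0.26 in pericyte-like cells, with none past the threshold. A 3' tag outside the deleted part of the gene is still counted after recombination, so these levels check neither the labels nor the deletion.

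Fewer of the recovered cells were astrocyte-like in the Ast KO libraries. Astrocyte-like cells made up 52.3%, 40.4% and 80.1% of fl/fl 1 to 3 and 14.8%, 29.2%, 27.0% and 9.84% of Ast KO 1 to 4. The groups did not overlap. The means were 57.6% ± 20.4 (SD, n = 3) and 20.2% ± 9.38 (SD, n = 4), a difference of -37.4 percentage points. The exact permutation p was 0.0286, the smallest that 35 splits allow, and the adjusted p over 12 classes 0.343. Endothelial-like cells took 5.42% ± 3.04 (SD) of fl/fl and 14.1% ± 5.41 (SD) of Ast KO libraries. Every Ast KO library (10.3 to 22.1%) lay above every fl/fl library (2.09 to 8.05%), with an exact permutation p of 0.0571 and an adjusted p of 0.343. Oligodendrocyte-like cells took 7.82% ± 1.47 and 14.7% ± 7.76 (exact p = 0.257), and microglia-like cells 8.02% ± 5.28 and 12% ± 1.69 (exact p = 0.20). The remaining 8 classes each took less than 5% of any library and had exact permutation p of 0.229 or more. No share passed the threshold after adjustment, and shares of dissociated cells also depend on how well each cell type was recovered. The clusters kept out by the later threshold held 2.09 to 3.58% of fl/fl and 0.569 to 4.81% of Ast KO libraries (cluster 5), and at most 0.0185% of any library but Ast KO 3 (cluster 33, 6.65%).

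**Figure D1:**
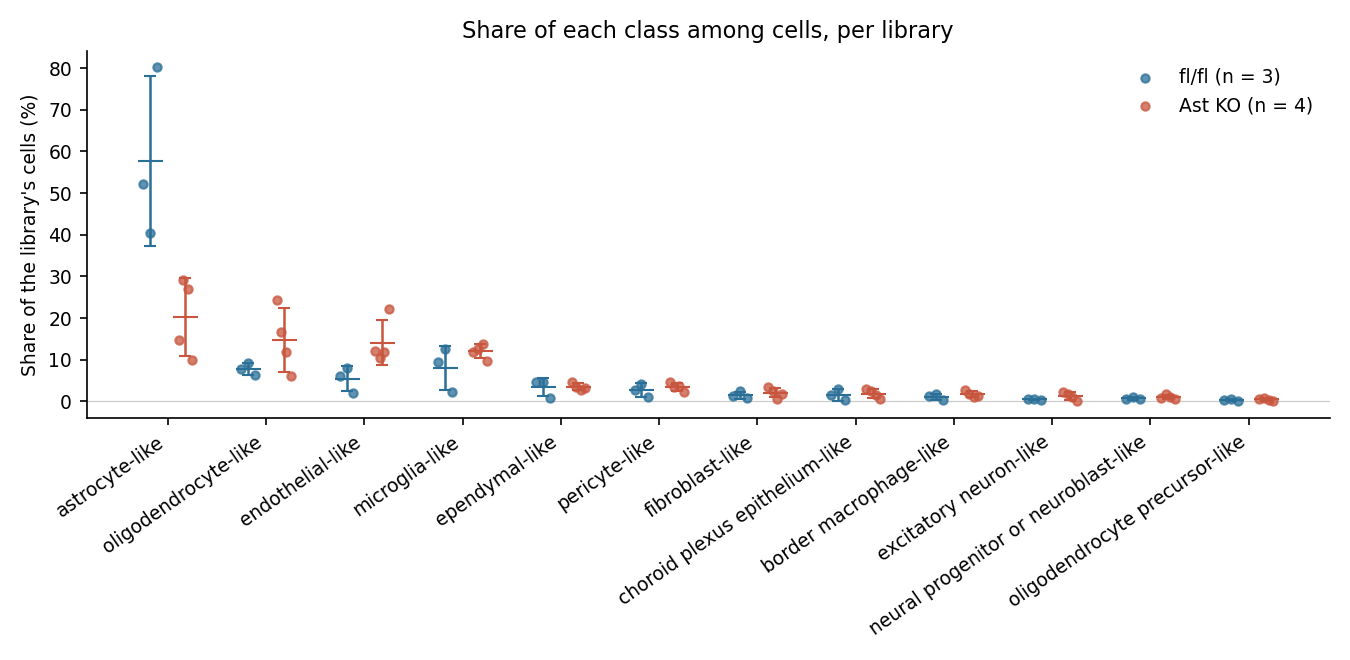
Share of each of the 12 classes among the cells of a library, in percent, for fl/fl (blue, n = 3) and Ast KO (red, n = 4); points are libraries, horizontal marks are means and error bars are SD. Astrocyte-like cells made up 40.4 to 80.1% of fl/fl and 9.84 to 29.2% of Ast KO libraries, and the other classes overlapped or lay closer together.

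In astrocyte-like cells the genes with the lowest p in the upward direction were the heat shock genes Hspa1a and Hspa1b, which encode inducible HSP70 chaperones. Hspa1a stood at 10.0 ± 2.66 CPM (SD) in fl/fl and 40.2 ± 15.5 CPM (SD) in Ast KO, and Hspa1b at 9.86 ± 4.26 and 37.7 ± 11.7 CPM. These genes are near-identical copies, so their counts cannot be assigned to either with certainty. Next by p were the transcription factor Plag1 (0.768 ± 0.114 and 2.70 ± 0.771 CPM), the efflux transporter Abcc4 (16.5 ± 1.36 and 25.5 ± 1.19 CPM) and Rgl2 (15.6 ± 2.10 and 26.9 ± 4.57 CPM). In the downward direction they were the ubiquitin ligase Rnf5 (116 ± 7.00 and 73.8 ± 10.6 CPM), the transcriptional repressor E2f6 (34 ± 3.88 and 23.3 ± 1.09 CPM) and the small GTPase Rnd2 (140 ± 14.1 and 88.6 ± 12.9 CPM). Next were Rbbp9 (44.1 ± 0.894 and 30 ± 3.78 CPM) and Carnmt1 (42.9 ± 1.69 and 31 ± 1.07 CPM). All 10 had no overlap between the libraries of the groups, and none passed the threshold (edgeR adjusted p = 0.571 for each). Of 14992 genes tested, edgeR called 0, with 580 higher and 666 lower at an unadjusted p under 0.05. DESeq2 called 2 higher genes, Hspa1a and Hspa1b, and 0 lower. The makeup of the class differed between libraries. Cluster 0, with few UMIs per cell, held 57.5% of the astrocyte-like cells of fl/fl 2, 56.6% of Ast KO 1 and 53.5% of Ast KO 2. In the other libraries no cluster held a majority: the largest was cluster 0 in fl/fl 1 (29.8%), cluster 1 in fl/fl 3 (28.3%) and cluster 4 in Ast KO 3 and Ast KO 4 (36.2% and 40.5%). Microglia markers in the astrocyte-like sums had a median log2 fold change of 1.53, endothelial markers of 1.10, erythroid markers of 1.99 and the astrocyte markers themselves of -0.27 (camera adjusted p = 0.00155, 0.00660, 0.0191 and 0.00660; adjusted p = 0.612 for each with an estimated correlation).

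Genes of energy metabolism lay lower in the astrocyte-like sums of Ast KO as groups, by small amounts per gene. Of 76 measured nuclear genes for respiratory chain subunits, 75 had a log2 fold change below 0 and 1 above, with a median of -0.34 (camera adjusted p = 3.85e-17, adjusted p = 0.505 with an estimated correlation). Examples were the ATP synthase gene Atp5g3 at 302 ± 16.4 CPM (SD) in fl/fl and 208 ± 30.6 CPM (SD) in Ast KO, and the complex I gene Ndufb10 at 331 ± 11 and 231 ± 53.2 CPM. Of 19 glycolysis genes 18 were below 0 (median -0.38, camera adjusted p = 1.69e-06, adjusted p = 0.505 with an estimated correlation), among them Pgk1 at 267 ± 9.90 and 187 ± 34.5 CPM and Ldha at 170 ± 29 and 125 ± 21.9 CPM. Of 13 respiratory chain genes encoded in mitochondria 11 were below 0 (median -0.17, camera adjusted p = 0.0471, adjusted p = 0.698 with an estimated correlation). For 28 genes of the mitochondrial nucleoid and of mitochondrial shape, which include the DNA packaging factor Tfam (26.6 ± 1.13 and 19.9 ± 3.38 CPM), the median was -0.10, and for 24 genes of mitophagy and autophagy, with Pink1 at 200 ± 13.6 and 141 ± 39.4 CPM, it was -0.25 (camera adjusted p = 0.0114 and 0.000583, adjusted p = 0.505 for each with an estimated correlation). The 27 genes of fatty acid oxidation and lipid droplets had a median of -0.29, and the 28 of the mitochondrial and integrated stress response a median of -0.23, with Hspa9 at 156 ± 24.6 and 110 ± 19.5 CPM (camera adjusted p = 6.02e-05 and 0.0114, adjusted p = 0.505 for each with an estimated correlation). No member of these 7 lists passed over all genes tested, and 0 passed adjusted over the list alone. Beside these lists the microglia markers stood at 1.53 and the astrocyte markers at -0.27 in the same sums. The microglia markers there summed to at most 10.4% of their level in the microglia-like sums of the same library. Within the 6 astrocyte-like clusters the nuclear respiratory chain list had medians from -0.27 to 0.08, with a mean of -0.05. The mean over these clusters was also closer to 0 than the whole-class median for glycolysis (-0.13), mitophagy (-0.09) and fatty acid oxidation (-0.15). The same held for the stress response list (-0.13) and the mitochondrially encoded genes (-0.10). Each cluster counted alike in these means, also where few Ast KO cells were present. Cluster 1 held 37, 146 and 46 cells in Ast KO 1 to 3, and Ast KO 4, with 6 cells, was left out of it.

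The genes behind the terms of the series title moved little. Of 27 measured genes of glycogen metabolism 18 were below 0 and 9 above, with a median log2 fold change of -0.10 (camera adjusted p = 0.104), and 0 passed over all genes or adjusted over the list alone. Phka2, a regulatory subunit of phosphorylase kinase, stood at 13.2 ± 0.38 CPM (SD) in fl/fl and 18 ± 1.65 in Ast KO. Ppp1r3c, which targets a phosphatase to glycogen, stood at 108 ± 23.6 and 75 ± 7.02, and the glycogen phosphorylase gene Pygm at 101 ± 28.2 and 79.3 ± 10.4. Of 28 genes for stress granule components 23 were below 0, with a median of -0.14 (camera adjusted p = 0.00488, adjusted p = 0.505 with an estimated correlation). Caprin1 stood at 85.3 ± 6.82 and 70.2 ± 4.16 CPM, and 0 members passed over all genes or adjusted over the list alone. These shifts lay beside those of the microglia markers (1.53) and erythroid markers (1.99) in the same sums. Within the 6 astrocyte-like clusters the mean of the medians was -0.11 for glycogen metabolism and -0.12 for stress granule components. Both were thus close to the medians of the whole class, and both lists lay below 0 in all 6 clusters.

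Lists of lipid synthesis, transport and protection lay lower as well. Of 23 cholesterol synthesis genes 22 were below 0, with a median of -0.37 (camera adjusted p = 2.04e-07, adjusted p = 0.505 with an estimated correlation). Of these, 4 fell when adjusted over the list alone, Pmvk (114 ± 48.2 and 56.3 ± 10.9 CPM), Sc5d, Idi1 and Cyp51, and 0 over all genes tested. The antioxidant list had 21 of 23 genes below 0 and a median of -0.35, with Sod2 at 269 ± 24.5 and 178 ± 38.2 CPM (camera adjusted p = 1.62e-05, adjusted p = 0.505 with an estimated correlation). The hypoxia list, which shares Pgk1 and Ldha with glycolysis, had a median of -0.21, and the list of glutamate and potassium handling, with glutamine synthetase Glul at 4180 ± 949 and 2966 ± 1026 CPM, a median of -0.25 (camera adjusted p = 0.0197 and 0.0150, adjusted p = 0.505 for each with an estimated correlation). Reactive astrocyte lists stayed short of the threshold. The pan-reactive list had 7 genes above and 8 below 0 (camera adjusted p = 0.444), the A1 list 7 and 5 (camera adjusted p = 0.460) and the A2 list 2 and 8 (camera adjusted p = 0.161). The astrocyte markers themselves had a median of -0.27 in these sums. Within the 6 clusters the mean of the medians was -0.25 for cholesterol synthesis, -0.14 for the antioxidant list, -0.13 for hypoxia and -0.13 for glutamate and potassium handling.

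Lists of immune genes and the blood-brain barrier list lay higher in the same astrocyte-like sums, where markers of microglia and endothelial cells also stood higher. The other vascular list, endothelial activation, had a median of -0.13 (camera adjusted p = 0.375) and lay below 0 in all 6 clusters. The complement list had 10 of 11 genes above 0 and a median of 1.55, and the list of interferon-stimulated genes 23 of 29 and 0.46 (camera adjusted p = 0.00283 and 0.0471, adjusted p = 0.505 and 0.786 with an estimated correlation). The list of inflammatory cytokines had 16 of 21 above 0 and a median of 0.78 (camera adjusted p = 0.0163, adjusted p = 0.532 with an estimated correlation). Tnf, a member of it, stood at 0.964 ± 0.924 CPM (SD) in fl/fl and 2.96 ± 1.88 CPM (SD) in Ast KO. The homeostatic and disease-associated microglia lists had medians of 1.26 and 0.66, the blood-brain barrier list 0.32 and the myelin list 0.40 (camera adjusted p = 4.97e-05, 0.0220, 0.0415 and 0.0235; adjusted p = 0.505, 0.660, 0.505 and 0.530 with an estimated correlation). All 4 haemoglobin genes were above 0, with a median of 2.21 (camera adjusted p = 0.00892, adjusted p = 0.505 with an estimated correlation). In the blood-brain barrier list 1 gene, Abcc4, rose when adjusted over the list alone, as did Hspa1a and Hspa1b in the list of dissociation response genes (25 measured, median 0.11, camera adjusted p = 0.444). Of all lists, 0 members passed over all genes tested. In total 8 lists were called higher and 12 lower with the preset correlation, and 0 with an estimated correlation or by fry. The number of higher calls depended on the libraries used: 1 list was called higher without Ast KO 1, 3 without fl/fl 1, and 4 without fl/fl 3 or without Ast KO 2. Against these, 7 were called higher without Ast KO 4, 11 without Ast KO 3 and 13 without fl/fl 2. The lower calls numbered 7 without fl/fl 3 and 10 to 13 without any other library. Without fl/fl 3 the interferon list turned to a median of -0.07. Within the 6 astrocyte-like clusters the mean of the medians was 0.21 for inflammatory cytokines and 0.15 for the blood-brain barrier list. It was 1.38 for complement, 0.50 for interferon-stimulated genes, 0.92 for homeostatic and 0.53 for disease-associated microglia genes, 0.51 for myelin and 2.69 for haemoglobin.

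**Figure D2:**
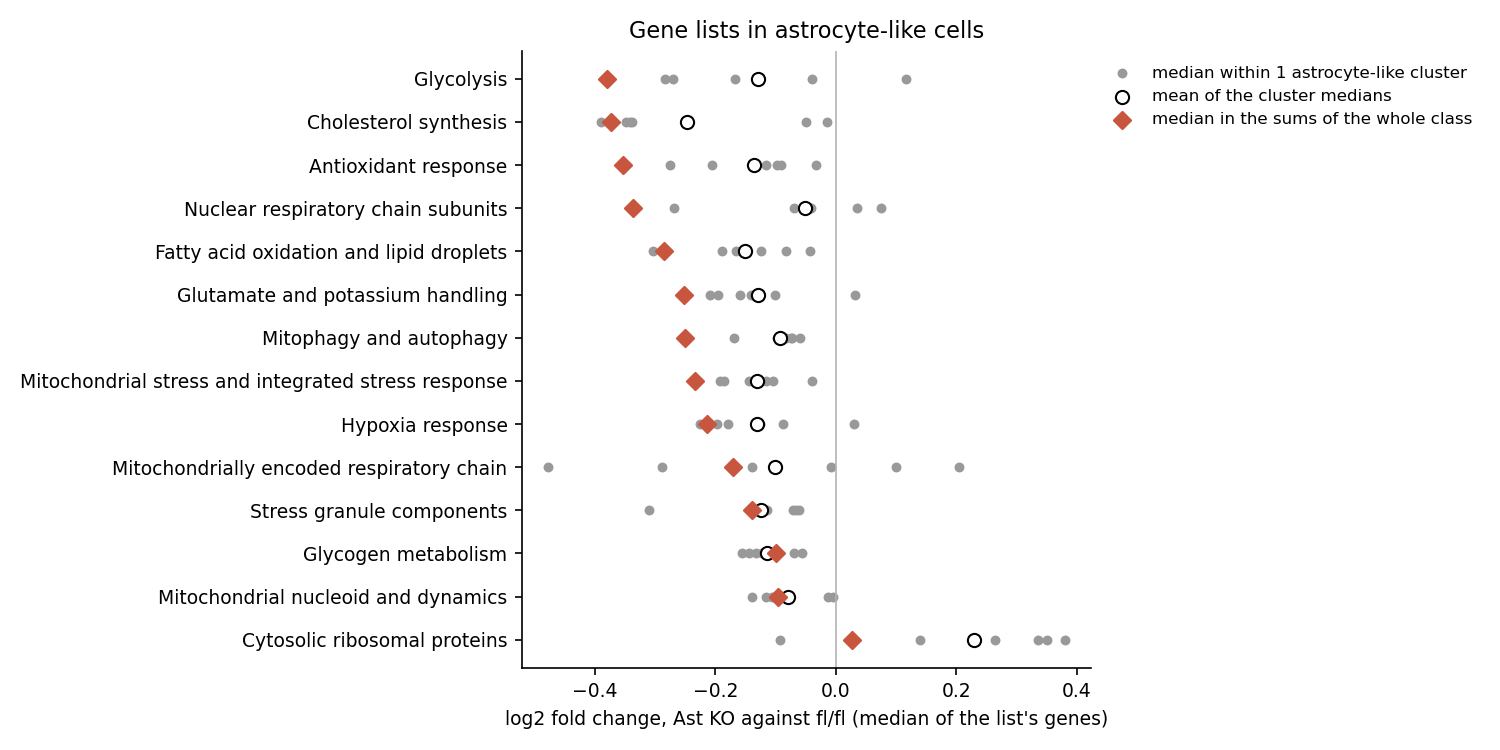
Median log2 fold change of the genes of 14 lists in astrocyte-like cells, Ast KO against fl/fl, in the sums of the whole class (red diamonds), in each of 6 astrocyte-like clusters (grey points) and as the mean of the cluster medians (open circles). The nuclear respiratory chain list lay at -0.34 in the whole class and at -0.05 as the mean of the clusters, and the glycogen list at -0.10 and -0.11.

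In microglia-like cells, as in astrocyte-like cells, edgeR called 0 of 13448 genes, with 475 higher and 929 lower at an unadjusted p under 0.05. DESeq2 called 19 higher and 119 lower. Astrocyte genes lay lower here. The astrocyte markers had a median log2 fold change of -1.62 in these sums. Of 17 measured genes of glutamate and potassium handling 15 fell when adjusted over the list alone (median -1.44, camera adjusted p = 2.20e-09, adjusted p = 0.452 with an estimated correlation). The homeostatic microglia genes were all above 0, 18 of 18, with a median of 0.33 (camera adjusted p = 0.000534, adjusted p = 0.452 with an estimated correlation). Tmem119 stood at 626 ± 104 CPM (SD) in fl/fl and 781 ± 60.6 CPM (SD) in Ast KO. Outside astrocyte-like cells, a rise of a class's own markers was not limited to microglia-like cells. The medians of these markers ran from -0.03 in endothelial-like to 0.65 in ependymal-like and 0.73 in border macrophage-like sums, with 0.22 in microglia-like sums. Less free astrocyte RNA in the total would also raise them, and was not separated from a change of the cells. The disease-associated list had 19 of 24 genes below 0 and a median of -0.03 (camera adjusted p = 0.156). Of them 2 fell when adjusted over the list alone, Ank (67.5 ± 12.2 and 42.2 ± 5.38 CPM) and Lgals3, which encodes galectin 3 (51.6 ± 9.11 and 33.1 ± 3.76 CPM). Interferon-stimulated genes had a median of 0.54, with 26 of 31 above 0, and genes of the dissociation response 0.51, with 25 of 26 above 0 (camera adjusted p = 0.00447 and 6.24e-06, adjusted p = 0.754 and 0.570 with an estimated correlation). Without fl/fl 3 the interferon list turned to a median of -0.11. Complement, antigen presentation and phagocytosis lists did not pass (camera adjusted p = 0.748, 0.787 and 0.622).

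Metabolic lists in microglia-like cells lay lower beside the astrocyte markers. Cholesterol synthesis had a median of -0.76 with 10 of 23 genes fallen when adjusted over the list alone, glycolysis -0.33 with 8 of 20, fatty acid oxidation -0.34 with 3 of 25 and the antioxidant list -0.36 with 3 of 23 (camera adjusted p = 4.33e-09, 5.22e-06, 3.73e-07 and 4.29e-05; adjusted p = 0.452 for each with an estimated correlation). The glycogen list had a median of -0.18, the astrocyte growth factor list -0.68 and the nuclear respiratory chain list -0.13 (camera adjusted p = 0.00447, 0.00746 and 7.48e-07; adjusted p = 0.452, 0.452 and 0.625 with an estimated correlation). Haemoglobin genes had a median of 4.76 and cytosolic ribosomal protein genes 0.25, with 75 of 75 above 0 (camera adjusted p = 0.000958 and 4.39e-06, adjusted p = 0.452 and 0.754 with an estimated correlation). With both fl/fl 3 and Ast KO 4 left out, the ribosomal list turned to a median of -0.07 (camera adjusted p = 0.148). In all, 5 lists were called higher and 8 lower with the preset correlation, and 0 with an estimated correlation or by fry. Without fl/fl 3 these were 2 higher and 10 lower. Without fl/fl 2, edgeR called 6 genes higher and 102 lower in microglia-like cells. All of these 102, and 4 of the 6, were at least 2-fold higher in astrocyte-like than in microglia-like sums.

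Whether the effect differed between astrocyte-like and microglia-like cells was tested directly. Of 15498 genes, edgeR called 0 for the difference, with 1277 at an unadjusted p under 0.05; no other tool was run. Without fl/fl 2 the test called 583 genes, 574 with a higher and 9 with a lower log2 fold change in astrocyte-like than in microglia-like cells. In the same setting 102 genes were called lower in microglia-like cells, all 102 at least 2-fold higher in astrocyte-like sums. A fall of free astrocyte RNA in microglia-like sums would also give this excess. The 583 calls therefore do not show that the knockout acts differently in the 2 cell types.

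Astrocyte transcripts were lower in every other tested class of the Ast KO libraries. The 15 astrocyte markers had median log2 fold changes from -1.66 in oligodendrocyte-like cells to -1.10 in fibroblast-like cells (camera adjusted p = 3.11e-24 and 7.10e-12; adjusted p = 0.363 and 0.416 with an estimated correlation). Relative to their level in the library's own astrocyte-like sums, they stood at a median over classes of 27.9%, 11.9% and 26.7% in fl/fl 1 to 3 and 7.46%, 10.5%, 11.2% and 10.6% in Ast KO 1 to 4.

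**Figure D3:**
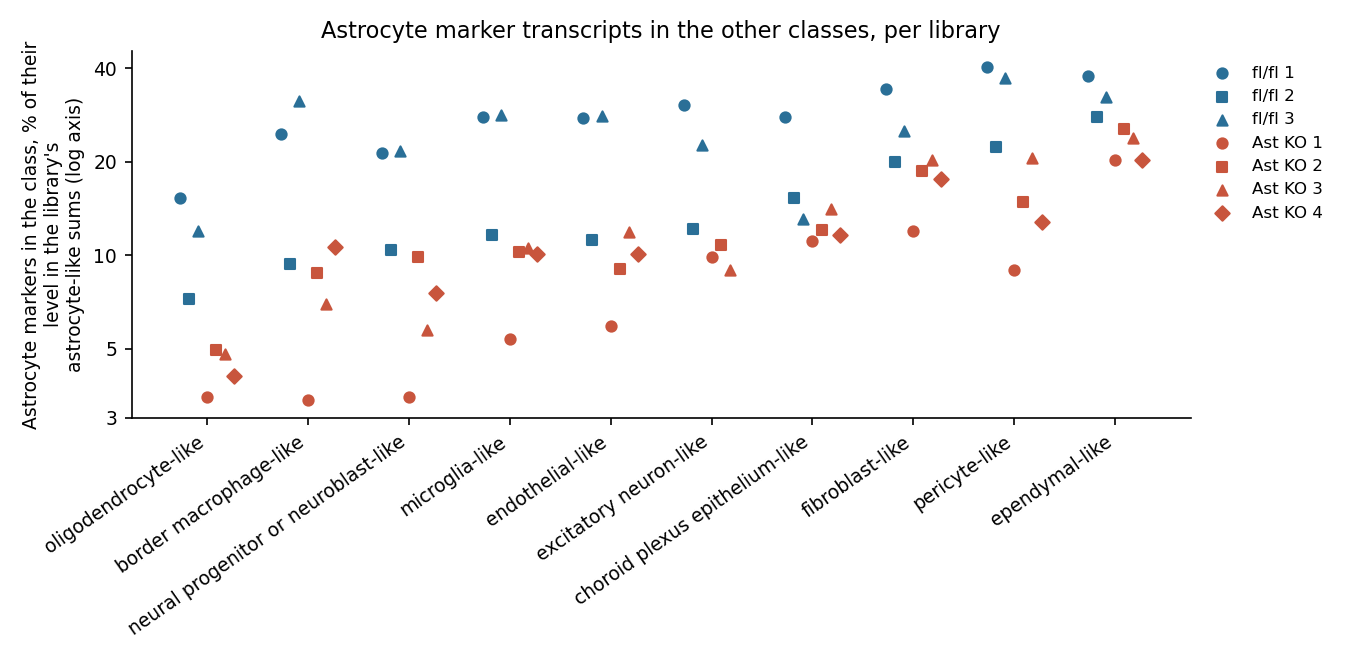
Level of astrocyte marker transcripts in 10 other classes, as a percentage (log axis) of their level in the astrocyte-like sums of the library; blue points are fl/fl 1 to 3 and red points Ast KO 1 to 4. The values of fl/fl 1 lie above those of the 4 Ast KO libraries in the plotted classes, and those of fl/fl 2 lie below those of fl/fl 1 in each of the 10.

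In ependymal-like cells, the ciliated lining of the ventricles, 211 genes rose and 217 fell of 13355 tested with edgeR (1524 and 1320 at an unadjusted p under 0.05). DESeq2 called 389 and 367. Among the genes that rose were Adam5 (5.65 ± 1.10 CPM in fl/fl, 19.3 ± 6.02 in Ast KO, SD; edgeR adjusted p = 0.0321), the peptidase gene Phex (7.37 ± 2.63 and 18.8 ± 5.72 CPM, adjusted p = 0.0489) and the neuropeptide Y receptor gene Npy2r (7.95 ± 4.32 and 22.5 ± 3.43 CPM, adjusted p = 0.0409). Among those that fell were the Notch target Hes5 (63.4 ± 35.1 and 11.3 ± 3.59 CPM, edgeR adjusted p = 0.0311), the astrocyte connexin gene Gjb6 (139 ± 69.0 and 24.5 ± 5.76 CPM, adjusted p = 0.0367) and the homeobox gene Dbx2 (71.5 ± 29.7 and 13.5 ± 7.10 CPM, adjusted p = 0.0404). Of the 217 genes that fell 185 (85.3%) were at least 2-fold higher in astrocyte-like than in ependymal-like sums, against 10.5% of all genes tested. The astrocyte markers had a median log2 fold change of -1.23. The calls depended on single libraries. EdgeR called 0 genes without Ast KO 1, 2, 3 or 4, 2 without fl/fl 1, 493 without fl/fl 2 (294 of them shared with the 428) and 1108 without fl/fl 3. Where 0 were called, the lowest adjusted p was 0.0560 to 0.0733, with 1269 to 1498 genes higher and 1091 to 1207 lower at an unadjusted p under 0.05. With doublets kept 22 genes passed, with thinned sums 224, and with sex as a covariate 197.

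In choroid plexus epithelium-like cells, which make cerebrospinal fluid, edgeR called 106 genes higher and 141 lower of 11361 (1285 and 1495 at an unadjusted p under 0.05). DESeq2 called 238 and 291. Clic3 (29.3 ± 15.6 CPM in fl/fl, 93.6 ± 18.2 in Ast KO, SD), Cltrn (14.5 ± 2.78 and 49.4 ± 15.3 CPM) and the transcription factor gene Dmrt3 (6.27 ± 1.39 and 17.7 ± 3.13 CPM) rose (edgeR adjusted p = 0.0449, 0.0400 and 0.0400). The chemokine gene Ccl5 (32.5 ± 31.0 and 0.660 ± 0.551 CPM), Synpo2 (26.2 ± 25.1 and 1.13 ± 1.03 CPM) and the cystine transporter gene Slc7a11 (54.4 ± 26.5 and 5.74 ± 2.20 CPM) fell (edgeR adjusted p = 0.0446, 0.0476 and 0.0400). Of the 141 genes that fell 115 (81.6%) were at least 2-fold higher in astrocyte-like sums, against 30.8% of all genes tested. The median of the astrocyte markers was -1.44. The class held 26 cells in fl/fl 3, and its cluster 29, with many UMIs per cell, came to 80.6% from fl/fl 2. EdgeR called 0 genes without cluster 29, 0 without fl/fl 1, Ast KO 2 or Ast KO 3, 1 without Ast KO 1 or Ast KO 4, 10 without fl/fl 2 and 2075 without fl/fl 3.

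In excitatory neuron-like cells, tested in 3 libraries per group, 1 gene rose and 0 fell of 10351 with edgeR (142 and 210 at an unadjusted p under 0.05), and DESeq2 called 2 higher. The gene called by edgeR was Resp18, a gene of endocrine and neuroendocrine cells, at 8.38, 23.7 and 19.2 CPM in fl/fl 1 to 3 and 168, 132 and 134 CPM in Ast KO 1 to 3, 8.13-fold higher (edgeR adjusted p = 0.0369). The astrocyte markers had a median of -1.23 and the microglia markers of 1.23 in these sums. Resp18 is also among the genes that lead the hormone cluster 33 of Ast KO 3. No gene passed without fl/fl 1, fl/fl 2, fl/fl 3, Ast KO 1 or Ast KO 2 (0 in each), or with sex as a covariate (0), while 1 gene, Resp18, passed without Ast KO 3.

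In endothelial-like cells edgeR called 0 of 12865 genes (511 higher and 580 lower at an unadjusted p under 0.05), and DESeq2 called 53 higher and 100 lower. The blood-brain barrier and endothelial activation lists had medians of 0.02 and 0.07 (camera adjusted p = 0.911 for each), and 0 of their members passed adjusted over the list alone. The activation genes Vwf, which encodes von Willebrand factor, and Lrg1 stood at 146 ± 27.5 and 52.3 ± 50.7 CPM (SD) in fl/fl and at 368 ± 287 and 399 ± 717 CPM (SD) in Ast KO. Cluster 17, led by Scgb3a1, Lrg1, Lcn2 and Vwf, held 93.8% of the endothelial-like cells of Ast KO 1 and 1.13 to 22.1% in the other libraries, where cluster 16 held 69.6 to 85.4%. The astrocyte markers had a median of -1.43 and the microglia markers of 1.2 in these sums. Without fl/fl 2 edgeR called 6 genes higher and 128 lower, all 128 and 1 of the 6 at least 2-fold higher in astrocyte-like sums.

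In oligodendrocyte-like cells the list of myelin and stress genes had 12 of 16 genes above 0 and a median of 0.24 (camera p = 0.0210, p = 0.0658 with an estimated correlation). Only 1 list was tested in this class, so adjustment over lists left these p-values unchanged. Mog stood at 1787 ± 206 CPM (SD) in fl/fl and 2221 ± 532 CPM (SD) in Ast KO, and Mal at 6709 ± 937 and 8564 ± 2416 CPM. Of the list, 0 members passed over all genes or adjusted over the list alone. EdgeR called 0 of 13287 genes (224 higher and 589 lower at an unadjusted p under 0.05), and DESeq2 called 5 higher and 177 lower. The list was not called without fl/fl 1 or without fl/fl 3. Without fl/fl 2 edgeR called 5 genes higher and 136 lower, all 136 and 4 of the 5 at least 2-fold higher in astrocyte-like sums. The median of the astrocyte markers was -1.66 and that of the microglia markers 1.18. The oligodendrocyte markers themselves had a median of 0.21. Less free astrocyte RNA in the total would also raise these and the myelin genes, and was not separated from a change of the cells.

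In the other classes edgeR called 0 genes. In pericyte-like cells, whose cluster 23 is led in part by the smooth muscle genes Acta2, Myl9 and Myh11, 346 genes were higher and 580 lower at an unadjusted p under 0.05, and DESeq2 called 9 and 104. In fibroblast-like cells these were 216 and 364, and 5 and 50 by DESeq2. In border macrophage-like cells, led by the antigen presentation genes H2-Aa and Cd74, they were 165 and 360, and 3 and 25 by DESeq2. Cluster 21, which makes up this class, also held 6 neutrophil markers (mean log2 fold 4.44, against 4.25 for its own markers), and at Leiden resolution 2 a neutrophil cluster of 98 cells lay apart from a border macrophage cluster of 938. In neural progenitor or neuroblast-like cells, led in part by the cycling genes Top2a and Pclaf, they were 140 and 257, and 1 and 4 by DESeq2. Without fl/fl 2 edgeR called 53 genes in pericyte-like and 24 in fibroblast-like cells. The astrocyte markers had medians of -1.51, -1.10, -1.60 and -1.53 in these 4 classes, and the microglia markers 1.26, 1.51, 0.35 and 1.88. In neural progenitor or neuroblast-like sums the microglia markers stood at 32.0 to 48.0% of their level in the library's microglia-like sums, except in fl/fl 3, where they stood at 1.60%. At Leiden resolution 2 a cluster of 214 cells led by cycling genes, with 7 microglia markers, lay apart from a progenitor cluster of 456 cells.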

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

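The tests of the named-class denominator, of the range of the fl/fl shares, of the variance held by library, of the genes at least 8-fold higher in astrocyte-like sums, of the astrocyte markers in their own class and of leaving out cluster 0 were chosen only after the result was seen. In the groups of 4 Ast KO libraries, a sample was picked out when its gap to the nearest other made up more of the group's range than Dixon's limit for 4 samples at the 95% level, which chance does in about 1 of 20 groups; 7 groups of 49 met this. Ast KO 4 was highest in the share of endothelial-like cells (22.1% against 10.3 to 12%, gap 0.862 of the range), in the median mitochondrial share (7.15% against 1.97 to 2.58%, gap 0.882) and in haemoglobin transcripts over all cells (10530 CPM against 1295 to 1895, gap 0.935). Ast KO 3 was highest in Dmrt3 in choroid plexus epithelium-like cells (22.3 CPM against 15.8 to 16.8, gap 0.847). In ependymal-like cells Ast KO 2 was lowest in Adam5 (10.4 CPM against 21.0 to 23.2, gap 0.830) and in Npy2r (17.4 against 23.9 to 24.5, gap 0.917), and Ast KO 1 in Phex (10.3 against 20.7 to 22.3, gap 0.869). Outside the named classes, clusters 25 and 33 held 9.26% and 6.65% of Ast KO 3, and cluster 32 held 38.1% of Ast KO 4, each at most 0.692% in any other library. No explanation was tested for these.

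The lower share of astrocyte-like cells in the Ast KO libraries has technical and biological candidate explanations. That the unnamed clusters of Ast KO 3 and Ast KO 4 fill the denominator is argued against as the whole cause: among cells of named classes the lowest fl/fl share still lay 10.3 percentage points above the highest Ast KO share (counting error 1.49). Among cells with at least 2000 UMIs this gap was 0.495 points (counting error 1.42), so a loss of shallow cells from the class stays open. Uneven recovery of astrocytes in dissociation also stays open, since the fl/fl libraries alone spanned 39.8 points, against a difference of 37.4 points between the groups. A loss of astrocytes after the deletion, or after a lesion that differed between samples, is the biological candidate and was not tested.

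Astrocyte transcripts were lower in all 10 other tested classes of the Ast KO libraries, which may reflect less free astrocyte RNA in suspensions with fewer astrocytes. The median marker ratio did not follow the astrocyte-like share throughout. It was 10.6% in Ast KO 4 (share 9.84%), 10.5% in Ast KO 2 (29.2%) and 11.9% in fl/fl 2 (40.4%). In fl/fl 1 and fl/fl 3 it was 27.9% and 26.7% (shares 52.3% and 80.1%). The library held 82.2% of the variance of the marker ratio after class means were removed (85.7% with the numerator alone), and 85.3% of the genes called lower in ependymal-like cells were at least 2-fold higher in astrocyte-like sums, values that free RNA needs. A change of single astrocyte genes inside microglia-like cells is argued against, since 98.9% of the genes at least 8-fold higher in astrocyte-like sums (436 of 441) were lower in the microglia-like sums of Ast KO. For the genes called higher in ependymal-like cells the test is void, because those genes were picked for their rise: their median log2 fold change exceeded that of all genes at least 2-fold lower in astrocyte-like sums by 0.35. A change in these classes themselves was not separated from free RNA.

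The nuclear respiratory chain genes lay lower in astrocyte-like sums, and a link to the mitochondrial function of Atad3a was not tested. A different makeup of astrocyte-like clusters has the value it needs within clusters. The list's median there averaged -0.052, although it was -0.27 in cluster 4. The clusters were, however, drawn from the same expression values. With cluster 0 left out the list's median was -0.42 in astrocyte-like sums, so the share of that cluster alone is not the cause. That share overlapped between the groups, at 24.5 to 57.5% of the class in fl/fl and 5.60 to 56.6% in Ast KO. Leaving cluster 0 out therefore does not test the other clusters. Cluster 1 held 14.85%, 5.68% and 28.3% of the class in fl/fl 1 to 3. In Ast KO 1 to 4 it held 2.72%, 5.30%, 1.79% and 0.560%. Cluster 1 was not left out. RNA of other cells in these sums stays open, as the astrocyte markers also had a median of -0.27. Microglia markers there summed to 6.79 to 8.44% of their level in microglia-like sums in fl/fl and 7.48 to 10.4% in Ast KO. Oligodendrocyte markers summed to 2.4 to 4.4% and 3.6 to 6.1% of theirs in oligodendrocyte-like sums. These low, overlapping levels argue against RNA of either cell type alone as the whole cause. The other cell types were not sized in this way. A fall of this size in every class is argued against, since the lower of the list's medians in oligodendrocyte-like and endothelial-like sums was 0.00659, but the list also lay lower in microglia-like (-0.13), pericyte-like (-0.14) and excitatory neuron-like sums (-0.21), so a part shared with some classes stays open. A direct effect of the deletion on these genes may add to the makeup of clusters and was not separated from it.

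Other splits of the same 7 libraries into 3 and 4 were run for each count. For choroid plexus epithelium-like cells 1 of 35 splits, the real split, gave as many genes (247, highest other 220, for fl/fl 1, fl/fl 2 and Ast KO 4 against the rest). The same holds for ependymal-like cells (428, highest other 62, for the same 3 libraries). Chance can be excluded for these 2 counts only at a share under 0.05 that is not adjusted over the 11 classes. The libraries fl/fl 1, fl/fl 2 and Ast KO 4 of the next split are those with cells of cluster 29 (30, 145 and 5 cells), and without that cluster edgeR called 0 genes in choroid plexus epithelium-like cells. For excitatory neuron-like cells 10 splits are too few for such a share (2 splits with as many, real value 1, highest other 1). For the gene lists chance cannot be excluded: 2 splits gave as many in astrocyte-like sums (20, highest other 21) and 13 in microglia-like sums (13, highest other 20). For the classes with 0 called genes and for the difference between astrocyte-like and microglia-like cells all 35 splits gave as many, which a real count of 0 fixes beforehand, so this says nothing about chance. The highest other counts were 10 (astrocyte-like), 3 (border macrophage-like), 5 (endothelial-like), 5 (fibroblast-like), 7 (microglia-like), 4 (neural progenitor or neuroblast-like), 19 (oligodendrocyte-like), 4 (pericyte-like) and 1 (the difference). In these 8 classes the highest other count came from parting fl/fl 3, Ast KO 3 and Ast KO 4, the libraries read as female, from the rest. Xist and the Y-linked genes part these libraries, so sex-linked genes may account for such counts. Which genes were called in that split was not examined.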

How the results depend on the processing

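Sex as a covariate, leaving out both fl/fl 3 and Ast KO 4 and leaving out single clusters were chosen only after the data were seen. Atad3a passed in no class and no share passed after adjustment under any alternative run. For the shares this says little, because the exact permutation test could hardly pass. With all 7 libraries its smallest p, 0.0286, became 0.343 after adjustment for astrocyte-like cells. With a library left out its smallest p is 0.1 (3 against 3 libraries) or 0.0667 (2 against 4), both above the threshold. An edgeR test of the cell counts, which has no such floor, gave astrocyte-like cells an adjusted p of 0.277. When each library was left out, the log2 fold change of Atad3a in astrocyte-like cells ran from -0.38 to -0.15. The difference of the astrocyte-like share then ran from -46.0 to -26.1 points. The numbers of called genes moved. With DESeq2 they were 2 (astrocyte-like), 28 (border macrophage-like), 529 (choroid plexus epithelium-like), 153 (endothelial-like), 756 (ependymal-like), 2 (excitatory neuron-like), 55 (fibroblast-like), 138 (microglia-like), 5 (neural progenitor or neuroblast-like), 182 (oligodendrocyte-like) and 113 (pericyte-like). With no filter on low counts they were 6 (border macrophage-like), 896 (choroid plexus epithelium-like), 930 (ependymal-like), 117 (excitatory neuron-like), 61 (fibroblast-like), 2 (neural progenitor or neuroblast-like), 2 (oligodendrocyte-like) and 41 (pericyte-like). With doublets kept, choroid plexus epithelium-like cells had 455 and ependymal-like cells 22; with sums thinned to the smallest library, 42 and 224, and excitatory neuron-like cells 2. At Leiden resolution 2, excitatory neuron-like cells had 0 and neural progenitor or neuroblast-like cells 2. With sex as a covariate the counts were 11 (choroid plexus epithelium-like), 197 (ependymal-like) and 0 (excitatory neuron-like). With both fl/fl 3 and Ast KO 4 left out they were 2357, 972 and 0 in these classes, and 0 lists were called in oligodendrocyte-like sums. With cluster 0 left out, 9 lists were called higher and 11 lower in astrocyte-like sums. With cluster 29 left out, choroid plexus epithelium-like cells had 0. With an estimated correlation and with fry, 0 lists were called in astrocyte-like, 0 in microglia-like and 0 in oligodendrocyte-like sums.

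The labels do not say whether the replicate numbers pair the samples, and the values do not decide it. Correlations of the deviations from the group mean for numbers 1, 2 and 3 were -0.24, 0.21 and 0.09 in astrocyte-like and -0.44, 0.03 and 0.17 in microglia-like sums. They were -0.22, 0.30 and -0.01 in endothelial-like and -0.30, 0.30 and 0.07 in oligodendrocyte-like sums, where fl/fl 1 and Ast KO 2 reached 0.51. The sex read from Xist and Y-linked genes was the same within each of these numbers. With the replicate block and Ast KO 4 left out, choroid plexus epithelium-like cells had 0 called genes, ependymal-like cells 0 and excitatory neuron-like cells 3; with no block and Ast KO 4 left out the first of these classes had 1 and ependymal-like cells 0, so the block is not needed for the loss there.

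Leaving out each library in turn, the numbers of called genes ran from 0 to 2075 (choroid plexus epithelium-like), 0 to 1108 (ependymal-like), 0 to 134 (endothelial-like), 0 to 24 (fibroblast-like), 0 to 108 (microglia-like), 0 to 141 (oligodendrocyte-like), 0 to 53 (pericyte-like), 0 to 1 (excitatory neuron-like) and 0 to 583 (the difference between astrocyte-like and microglia-like cells), and were 0 throughout in the other classes. The numbers of lists ran from 11 to 26 in astrocyte-like, 12 to 18 in microglia-like and 0 to 1 in oligodendrocyte-like sums. The interferon list ran from -0.070 to 1.04 in astrocyte-like and from -0.11 to 1.30 in microglia-like sums, below 0 without fl/fl 3 alone. With both fl/fl 3 and Ast KO 4 left out, the list of cytosolic ribosomal proteins turned to -0.12 in astrocyte-like sums (camera adjusted p = 0.00794) and -0.068 in microglia-like sums (camera adjusted p = 0.148), and the interferon list stood at -0.05 in microglia-like sums. These p-values used the preset correlation of 0.01, and a test with an estimated correlation was not run in this setting. Over all 7 libraries the estimated correlation of the ribosomal list was 0.84 in astrocyte-like and 0.88 in microglia-like sums. Of single lists, 83 values lost and 17 gained a call under other alternatives, and 39 and 35 when a library was left out; of named genes, 55 and 2, and 71 when a library was left out. Signs changed with no call in 53 values of lists, 30 of named genes, 18 of Atad3a and 10 of shares. The cause was not tested. Depth limits the Ast KO astrocyte-like sums, with 79 to 207 UMIs of Atad3a per library against 301 to 922 in fl/fl.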

Other observations

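Cells outside the named classes included macrophage-like clusters led by Spp1, Gpnmb and Lyz2. Cluster 15 (2312 cells, led also by Apoc2, Cd5l and Ms4a7) held 2.30%, 5.19% and 0.289% of fl/fl 1 to 3 and 5.12%, 4.77%, 3.66% and 1.91% of Ast KO 1 to 4. Cluster 11 (394 cells, led also by Hmox1 and Lgals3) held 0.323%, 0.496% and 0.00963%, and 1.68%, 0.7%, 0.786% and 0.0826%. Both had more leading markers of monocytes or macrophages than of the class that matched best. Cluster 20 (1264 cells), led by Npy, Fabp7, Frzb and Foxd3, held 0.915 to 2.52% of fl/fl and 0.0210 to 3.98% of Ast KO libraries, and cluster 2 (749 cells) 0.543 to 2.43% and 0.138 to 1.17%. Over all cells of Ast KO 3, the hormone genes Gh and Prl that lead clusters 25 and 33 stood at 19736 and 6454 CPM.

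In endothelial-like cells, cluster 17 (1265 cells) came to 81.9% from Ast KO 1. Lists that did not pass in astrocyte-like sums and are not given with the comparisons were antigen presentation (median 0.28, camera adjusted p = 0.108), phagocytosis and lysosome (0.17, 0.354), astrocyte growth and synapse factors (-0.12, 0.444), sex-linked genes (-1.23, 0.562), cycling cells (0.04, 0.867) and cytosolic ribosomal proteins (0.03, 0.976). In microglia-like sums these were stress granule components (-0.02, 0.622), mitochondrially encoded respiratory chain (-0.44, 0.121), mitochondrial nucleoid and dynamics (-0.10, 0.209), mitochondrial and integrated stress response (-0.18, 0.0628), mitophagy and autophagy (-0.06, 0.336), pan-reactive (-0.35, 0.121), A2 (-0.39, 0.137), hypoxia (-0.27, 0.0502), inflammatory cytokines (0.27, 0.236), blood-brain barrier (0.34, 0.144), myelin (0.25, 0.121), cycling cells (-0.15, 0.336) and sex-linked genes (-0.87, 0.663). In microglia-like sums the A1 list (median 0.07, camera adjusted p = 0.677) and the endothelial activation list (0.09, 0.739) had a median above 0 while the test pointed down, and the complement (0.12) and antigen presentation (0.13) lists had a median above 0 and a mean below 0.

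Other marker lists in astrocyte-like sums that passed were those of border macrophages (median 1.16, camera adjusted p = 0.00660), pericytes (0.50, 0.00660), oligodendrocytes (0.39, 0.0143) and monocytes (0.81, 0.0177), each with an adjusted p of 0.612 with an estimated correlation. The list of oligodendrocyte precursors had a median of 0.19 while the test pointed down (camera adjusted p = 0.930). The other 10 lists had camera adjusted p from 0.0613 to 0.930.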
